A study of Caenorhabditis elegans with 2 samples.

How the data were processed

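The series holds ChIP-seq of GFP-tagged ELT-3 in 2 libraries of whole L1 larvae, and the labels name the libraries biological replicates 1 and 3. The labels differ between the libraries in the source of the worms and in what they record of fragmentation. Replicate 3 is noted as sonicated with a microtip, and for replicate 1 a size range is given instead. No extraction protocol is given in the labels. Per the deposited manifest, each list of candidate regions was made from alignments of a library, or of both pooled, and a control file shared by both libraries, and the thresholded list was then derived from the lists of replicate 1, replicate 3 and the pool. The aligner, peak caller and filters are not given in the sources used here. The deposited lists come in builds ce10 and ce11. All analyses with coordinates used the ce11 lists, with the ce10 lists as an alternative where no reference was needed.

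The deposited signal column is, by its place in the narrowPeak format, the peak caller's measure of the strength of a region. Its scale differs between lists, so signals were compared across lists by rank or correlation only. The deposited −log10 column is −log10 of the q-value of a region. It was constant, 3.86, in the thresholded list, so it could not rank those peaks. Each list gives intervals, a summit position, and both values. No column was left unmapped. The pooled and replicate 1 lists held 30000 regions each and that of replicate 3 held 24854. The lists carry no read counts, so library depth is unknown and no interval that needs it is given. Peaks that overlap a region of replicate 3 were counted because the thresholded list itself does not say which library a peak rests on.

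Genes were taken from Ensembl release 115 on WBcel235, the assembly named ce11 by genome browsers, with sequence from the same assembly, and no region ran past a chromosome end. A coding gene was counted as having a peak when a nuclear thresholded summit lay within 1000 bp upstream to 500 bp downstream of the 5′ end of its longest annotated extent. A summit could count for several genes. The 18 gene lists were compared with all other coding genes, 19973 genes in all, by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment over the 18 lists, and 3 classes of RNA genes were compared with the coding genes in the same way. These tests treat genes as the units, and genes are not replicates of the experiment. The share of summits near 5′ ends was set against 1000 circular shifts of the peaks along each chromosome, and annotated locations against 100. WGATAR sites were sought on both strands within 50 bp of each summit and in windows of the same length 500 bp to each side, with exact McNemar tests against each side, of which the higher p is given. All 2080 distinct 6-mers were tested between summits and flanks by Fisher's exact test. Intervals of shares are exact binomial (Clopper-Pearson) 95% intervals. Region overlap required at least 1 bp. The 24 thresholded peaks on mitochondrial DNA were left out of all comparisons with genes or sequence.

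The gene lists, tests, windows, alternatives and the rule for genes named in the text were chosen before the data were examined. The rule takes the 25 coding genes whose windows hold the highest-signal summits, up to 4 members of each list with the highest signals, and elt-3 and unc-119. Alternatives were other windows, whole-peak overlap, assignment to the nearest gene, the peaks of higher signal alone, each replicate alone (its own 2940 strongest regions), a background of named genes, random lists matched on upstream distance, linked members counted once, other motifs and flanks, and chromosome length as the expectation for X. Added after seeing the data were peaks with a region in each replicate's list, peaks with or without WGATAR, summits inside or outside the 5′ windows, the correlation over nuclear peaks only, every alternative for the RNA gene classes, and the counts of regions in the 40 kb around elt-3 and unc-119. Those counts were set against 1000 random windows of the same length, less 2 that overlapped the tested window.

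The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The tests were checked on simulated data. Peaks were placed at random over the 19973 coding genes, with raised odds planted in the molting and ribosomal protein lists. These lists were called in 96 and 100 of 100 runs, and 0.417% of the tests of lists without a planted effect gave a call. The odds planted for molting were above the 4.23 seen in the data, so its 96 runs do not give the power at that size. Genes were drawn independently, whereas neighbouring genes often share a peak, so the 0.417% does not carry over to the data. Over 3000 random places the WGATAR ratio was 0.952 and 0 6-mers were enriched, and a planted GATAAG ranked 1st. Random places lack the difference in GC content between summits and flanks seen in the data (43.1% against 35.7%). This check therefore does not cover its effect on the motif and 6-mer tests.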

Results

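Binding of the transcription factor ELT-3 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole first-stage (L1) larvae of *Caenorhabditis elegans*. ELT-3 is a GATA-type zinc-finger protein of the epidermis, the tissue that secretes the collagen cuticle. The larvae, of mixed sex, came from strain OP75, an unc-119 mutant strain whose transgene wgIs75 expresses ELT-3 fused to GFP. The antibody field of the labels reads elt-3 and the description eGFP-elt-3, so the labels do not settle whether the antibody recognised GFP or ELT-3 itself. The labels give 1 group of 2 libraries, biological replicates 1 and 3, and no other genotype or stage, so no difference between groups could be tested. The submitters' list of peaks that passed their reproducibility threshold, called thresholded peaks here, held 2940 regions in build ce11, of which 2916 lay on nuclear chromosomes. These 2940 were exactly the 2940 regions of highest signal in the list called on the pooled libraries. Their signal values ran from 34.2 to 1090 with a median of 53.5, and they covered 0.945% of the genome. The lists give no read counts, so the depth of each library is unknown, and intervals below cover the counting of peaks or genes only.

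The gene that was tagged held peaks in its own introns. Within elt-3 on chromosome X (13934874 to 13941216, ce11) 4 thresholded peaks had summits in introns, and the strongest (13937369 to 13937702) had a signal of 169.8 and ranked 89th of 2940. That peak and the one with its summit at 13939550 (signal 112.3) held GATA sites within 50 bp of the summit and overlapped regions of replicate 3, ranked 265 and 202 in its list. The other 2, with signals of 66.3 and 96.4, held no such site and overlapped no replicate 3 region. Candidate regions were crowded around elt-3, 47 in 40 kb of the pooled list against a median of 11 in random windows, and the copy number of the transgene is not known from the lists. No thresholded summit lay within 1000 bp upstream to 500 bp downstream of the annotated 5′ end of elt-3, the window used for all genes here. Around unc-119 on chromosome III, the gene mutated in this strain, the nearest thresholded summit was 20448 bp from the 5′ end.

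Of the 25 strongest nuclear peaks, 5 lay in the window of a ribosomal protein gene, and 12 lay in that of no coding gene, 8 of them on X. The highest was 276 bp upstream of rpl-3, a large-subunit ribosomal protein gene (signal 490.4), followed by 1 lying 154 bp upstream of cdc-48.1, which encodes a protein-unfolding ATPase (446.4). A peak of signal 381.0 lay 582 bp upstream of egg-5, next to a spliced-leader RNA gene, sls-2.4. Other peaks among those of the 25 coding genes with the highest signal lay at rpl-20 (328.0), rpl-35 (325.1), iff-2 (304.3), an initiation factor 5A gene, and rpl-15 (286.4). The same 25 genes included pdi-3 and ubql-1, which share a peak of 273.8, rps-12 (258.0), sec-61.G (247.5), imb-3 (239.6), his-37 (235.1), lin-54 and rpl-12 with a shared peak of 227.1, bag-1 (225.9) and tos-1 (215.0). Adjacent genes often shared a peak, so the 25 genes rested on 18 peaks. None of those 18 held a WGATAR site (W, A or T; R, A or G), the sequence that GATA factors recognise, within 50 bp of the summit, and 17 overlapped a region of replicate 3. Of the 25 strongest nuclear peaks, 5 held a WGATAR site, each in the window of no coding gene.

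Summits gathered near the 5′ ends of genes. Of the nuclear summits 49.9% (1456 of 2916) lay in the window of a protein-coding gene, against a mean of 25.9% and a highest value of 28.7% in 1000 circular shifts of the peaks along their chromosomes (one-sided permutation test, p = 0.001, the smallest those shifts can give). Intergenic summits made up 61.9%, against a mean of 33.4% after 100 such shifts. Coding exons held 1.85% of summits against 24.4% after shifting, and introns 24.1% against 33.6%. Summits inside tRNA, snRNA, snoRNA or rRNA genes were few, 71 (2.43%), but shifted peaks fell there at 0.119%. In all, 1878 of 19973 coding genes had a thresholded peak in their window. The 2940 strongest regions of replicate 3 alone gave 34.2% of summits in windows and 1173 genes.

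Genes of tyrosine breakdown, molting, epidermal defence peptides and epidermal transcription factors carried peaks more often than other coding genes with the main window and background. Against named genes only, tyrosine breakdown kept the call (odds ratio 14.9, adjusted exact p = 0.0144), while molting (3.27, 0.0636), the peptides (3.45, 0.0678) and the transcription factors (3.20, 0.0729) lost it. For tyrosine catabolism 4 of 6 genes had a peak: hgo-1 (signal 156.2), fah-1 (115.2), gst-42 (76.1) and tatn-1 (63.1), enzymes that carry tyrosine to fumarate and acetoacetate. Each of these 4 peaks held a WGATAR site. Their odds ratio against all other coding genes was 19.3 (95% interval 2.76 to 213.5; Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over the 18 lists, adjusted exact p = 0.0060). In replicate 3 alone the odds ratio was 3.21 (adjusted exact p = 0.783), and with only peaks that had a region in each replicate's list it was 8.66 (adjusted exact p = 0.0994).

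Molting genes had peaks at 7 of 23 (odds ratio 4.23, adjusted exact p = 0.0183). They included noah-1 (49.1), a cuticle-attached ZP-domain protein, the kinase gene nekl-2 (41.99), the receptor-type tyrosine kinase gene rol-3 (39.4) and the nuclear receptor gene nhr-25 (40.2). Of the antimicrobial peptide genes, 6 of 19 had a peak (odds ratio 4.46, adjusted exact p = 0.0228), with nlp-31 and nlp-34 at the same peak (126.7), nlp-33 at 59.98 and cnc-8 at 49.3. Of the epidermal transcription factor genes, 6 of 20 had a peak (odds ratio 4.14, adjusted exact p = 0.0251), among them blmp-1 (51.4), nhr-25, sta-2 (39.5) and hbl-1 (37.3). The molting and transcription factor lists share members with a peak, nhr-25 among them, so their calls are not independent. The blmp-1 summit, in an intron 377 bp downstream of the 5′ end, had 4 WGATAR sites. A window of 500 bp upstream to 250 bp downstream ended the call for molting (3.56, adjusted exact p = 0.0807) and the transcription factors (3.20, 0.158). For the latter so did one reaching 2000 bp upstream (3.04, 0.0667) and peaks with WGATAR only (4.69, adjusted exact p = 0.173). With linked members counted once, the transcription factors were at 3.17 times random lists (adjusted p = 0.0617 by a permutation test). Histones had a smaller p by that test at a lower ratio (2.07, 0.0240), so it does not settle the call. Among the 1470 peaks of highest signal, none lay at a molting or epidermal transcription factor gene, and the peptides lost the call (3.56, adjusted exact p = 0.240). With only peaks that had a region in each replicate's list, molting (3.65, adjusted exact p = 0.0994) and the transcription factors (4.33, 0.0960) lost it. In replicate 1 alone, molting fell to an odds ratio of 3.40 (adjusted exact p = 0.0773), the peptides to 3.44 (0.101) and the transcription factors to 1.70 (0.550). In replicate 3 alone, molting (4.47, adjusted exact p = 0.0432) and the peptides (7.43, 0.0034) kept the call and the transcription factors (4.02, 0.0971) did not.

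Structural genes of the cuticle and epidermis did not pass the test as lists. Cuticle collagens had peaks at 21 of 176 genes (odds ratio 1.31, interval 0.786 to 2.08, adjusted exact p = 0.324), the highest at col-147 (118.7), dpy-10 (96.9), col-62 (92.7) and col-159 (90.1), each with 1 WGATAR site. Counting only peaks with a WGATAR site, a choice made after the data were seen, gave collagens an odds ratio of 3.13 (adjusted exact p = 0.0052). Collagen processing had 3 of 12 (pdi-2, dpy-11 and dpy-31; odds ratio 3.21, adjusted exact p = 0.216). Epidermal junctions and attachments had 4 of 21 (spc-1, mup-4, mua-6 and dlg-1; 2.27, 0.258). In replicate 3 alone no member of either of these lists had a peak, while the window from 2000 bp upstream gave both the call (5.07, adjusted exact p = 0.0277, and 4.37, 0.0089). Osmotic and oxidative stress genes had 5 of 22 (2.84, 0.128), among them wdr-23 (120.4), osm-11 (63.8), tps-2 (49.2) and gpdh-1 (37.6). Giving each summit to the nearest gene only gave this list the call (3.84, adjusted exact p = 0.0447). Cuticlins and ZP-domain genes had 1 of 42 (noah-1; 0.235, 0.286), with an odds ratio of 1.23 in replicate 3 alone (adjusted exact p = 0.960), and hedgehog-related genes 4 of 86 (grl-11, hog-1, grl-26 and wrt-3; 0.469, 0.286), which became 5 of 86 and 0.989 in replicate 3 alone (adjusted exact p = 1). The GATA factor genes as a list, elt-3 among them, had 0 of 11 with a summit in the window (adjusted exact p = 0.691), and an odds ratio of 1.60 in replicate 3 alone (adjusted exact p = 0.960).

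Ribosomal protein genes carried peaks far more often than other coding genes. A peak lay at 60 of 78 of them (76.9%, against 9.14% of other coding genes; odds ratio 33.1, interval 19.2 to 59.8, adjusted exact p = 7.4e-45). Giving each summit to the nearest gene only lowered this to 35 of 78 and an odds ratio of 10.8 (adjusted exact p = 4.0e-19), and replicate 3 alone gave 7.25 (adjusted exact p = 1.5e-10). Counting only peaks with a WGATAR site ended the call (2.90, adjusted exact p = 0.0903). Chemoreceptor genes, which are expressed in sensory neurons, had peaks at 10 of 1216 (odds ratio 0.0750, adjusted exact p = 1.4e-38), the highest at srh-17 (99.99), and replicate 3 alone gave 0.335 (adjusted exact p = 1.8e-09). Lists for other tissues did not pass. No intestine gene of 27 had a peak (adjusted exact p = 0.286), muscle had 1 of 36 (unc-112; odds ratio 0.275, 0.324), neurons 3 of 36 (snb-1, unc-18 and syd-2; 0.876, 1), the germline 3 of 64 (mex-1, cgh-1 and spn-4; 0.473, 0.336) and histones 6 of 72 (0.876, 1), with his-37, his-67, his-68 and his-31 the highest. Muscle had an odds ratio of 0.457 in replicate 3 alone and 0 of 36 in replicate 1 alone, and neurons 0.943 and 0.565. Giving each summit to the nearest gene put neurons at 1.18 (adjusted exact p = 0.834). Histone genes lie in 20 clusters, and with linked members counted once the direction turned (4 clusters with a peak, 2.07 times random lists, adjusted p = 0.0240 by a permutation test). That p is not taken as a call, since epidermal junctions, at 2.15 times random lists with as many clusters, had 0.192 by the same test.

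**Figure D1:**
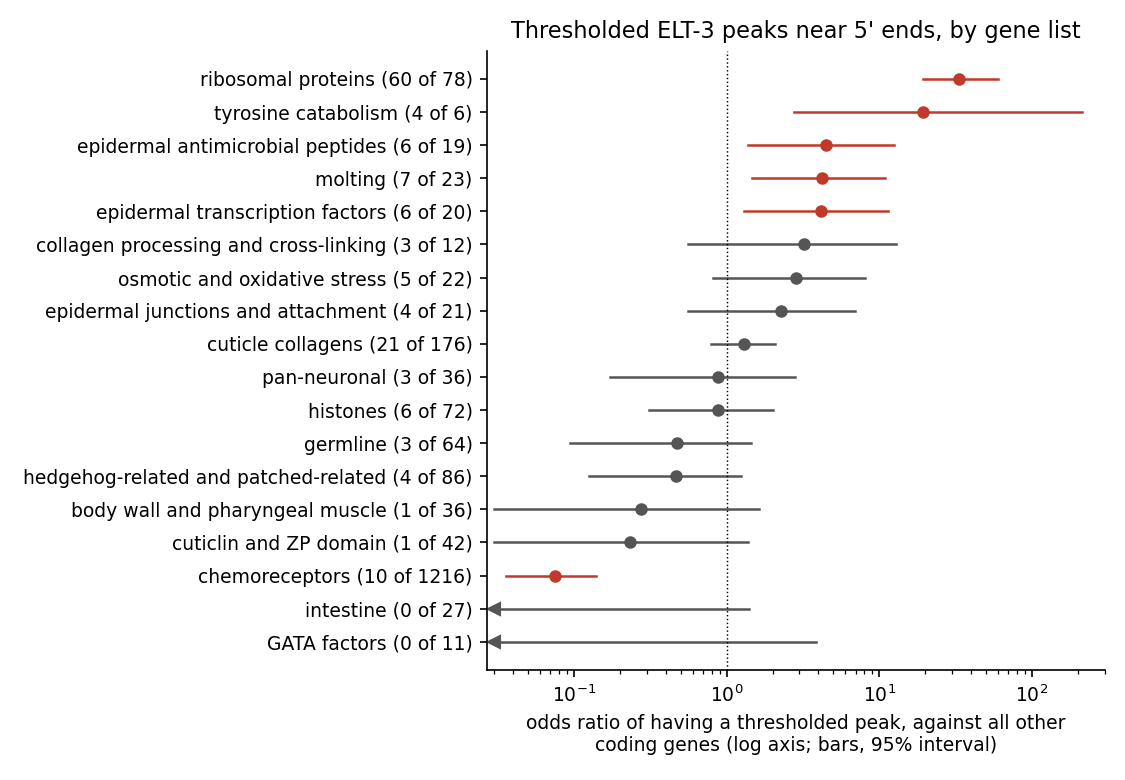
Odds ratio of having a thresholded peak within 1000 bp upstream to 500 bp downstream of the 5′ end, for each of 18 gene lists against all other coding genes (log axis; bars, 95% intervals, clipped where they reach the left edge; triangles, lists with no peak; red, adjusted p below 0.05). With these windows and peaks, ribosomal proteins lie highest at 33.1 and chemoreceptors lowest, at 0.0750, of the lists with a peak.

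Genes for small structural RNAs also carried peaks. Of the tRNA genes, 156 of 612 had a summit in their window (25.5%, against 9.40% of coding genes; odds ratio 3.30, adjusted exact p = 1.8e-29 by Fisher's exact test). For snoRNA genes, which encode guides for RNA modification, it was 117 of 346 (4.92, adjusted exact p = 2.1e-34), and for snRNA genes 27 of 129 (2.55, adjusted exact p = 0.00010). WGATAR sites were no more frequent at the summits close to these genes than beside them. Within 100 bp of snoRNA genes, 4.05% of 74 summits had a site, against 23.6% of their flanking windows. At tRNA genes it was 20.7% of 121 against 26.0%, and at snRNA genes 7.69% of 26 against 15.4%.

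GATA sites were enriched at summits, more so away from 5′ ends. A WGATAR site lay within 50 bp of 34.8% of nuclear summits (interval 33.1 to 36.6), against 20.97% of windows 500 bp to either side, a ratio of 1.66 (p = 6.0e-28 by the exact McNemar test against the flank with the higher p). Summits outside the 5′ windows had a site at 41.4% against 21.9% (ratio 1.89), and intronic summits at 43.2%. Summits inside the windows had it at 28.3% against 20.1% (1.41). The odds ratio of a site, summits outside against inside, was 1.79 (interval 1.53 to 2.09, p = 1.4e-13 by Fisher's exact test). The share did not rise with peak signal: it was 36.1% in the fifth of peaks with the highest signal and 34.99% in the fifth with the lowest. In replicate 3 alone the share was 23.9% against 21.4% (ratio 1.12, exact p = 0.0496).

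Other short sequences ranked above GATA at summits by p. Of 2080 6-mers, 750 were more frequent at summits than in flanks and 521 less frequent (adjusted p below 0.05, Fisher's exact test). GAGAGA ranked first, at 25.1% of summits against 5.59% of flanks, and ACGCAG had the higher ratio, 7.07 (13.3% against 1.89%). GATAAG, a core GATA-factor sequence, ranked 11th by p (14.3% against 3.91%, ratio 3.66). Some 6-mers ranked above GATAAG had lower ratios, such as AGAGAA (2.79). GC content was 43.1% at summits and 35.7% in flanks, a difference for which the ranking was not corrected. In replicate 3 alone 161 6-mers were enriched, with GAGAGA again first (ratio 1.89) and GATAAG again 11th (1.82).

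**Figure D2:**
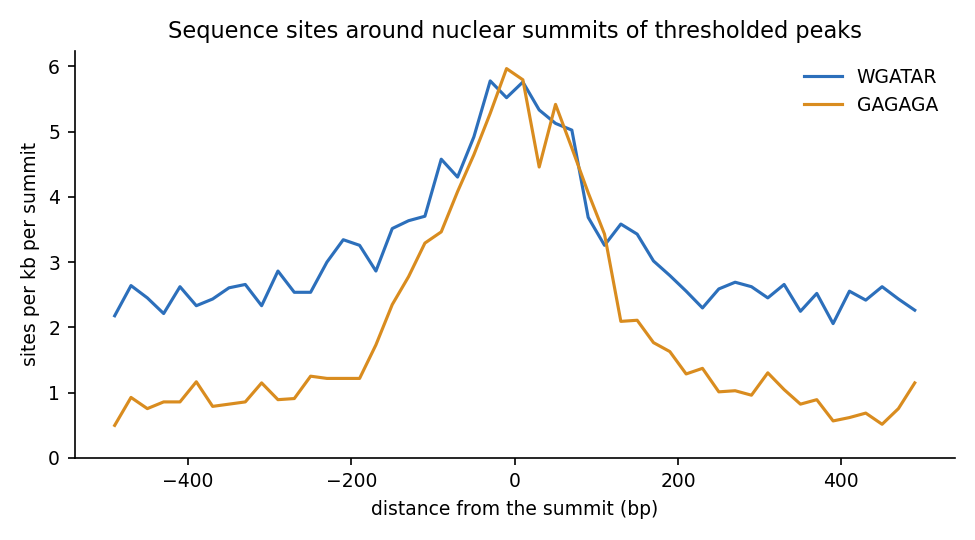
Number of WGATAR and GAGAGA sites per kb of sequence per summit (vertical axis) by distance from the summit in bp (horizontal axis), over the 2916 nuclear thresholded peaks. Both kinds of site are most frequent close to the summit.

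Chromosome X held more peaks than its share of genes. It had 611 of the 2916 nuclear peaks (20.95%) and 13.7% of coding genes, an odds ratio of 1.67 (interval 1.51 to 1.85, p = 2.4e-23 by Fisher's exact test). The odds ratio was 2.18 for summits outside the 5′ windows and 1.22 for those inside them. Both take coding genes as the expectation, while X holds 17.7% of the nuclear length. With chromosome length as the expectation, all nuclear peaks gave 1.24 (interval 1.13 to 1.35). Per Mb, X had 34.5 peaks, chromosome I 33.5, chromosome III 32.2 and chromosome V the fewest, 21.5.

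The 2 libraries shared part of their strongest regions. Of the 2940 highest regions of replicate 1, 708 (24.1%, interval 22.5 to 25.7) overlapped one of the 2940 highest of replicate 3 by at least 1 bp. For nuclear regions it was 23.8%, against at most 2.74% in 1000 circular shifts. Nearly every thresholded peak, 99.7%, overlapped a replicate 1 region, and 58.7% overlapped any of the 24854 regions of replicate 3. That share fell from 78.3% in the fifth of nuclear peaks with the highest signal to 46.3% in the lowest. Across the 1722 peaks with a region in both lists, Spearman's rho between the replicates' signals was 0.336. It was between 0.250 and 0.394 on each nuclear chromosome. These correlations are across regions, which are not independent replicates. The thresholded signal followed replicate 1 (rho 0.951 across 2909 nuclear peaks) more closely than replicate 3 (0.375 across 1709).

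**Figure D3:**
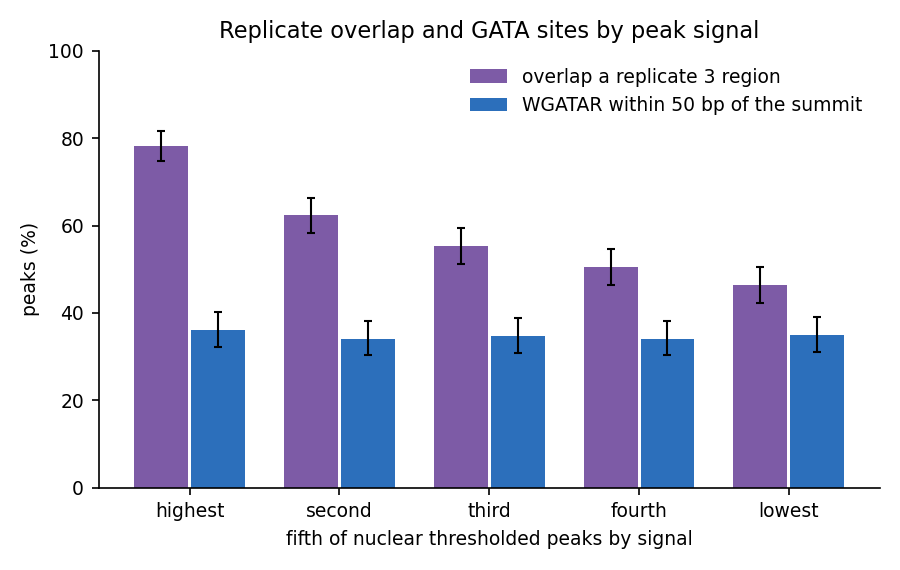
Share of nuclear thresholded peaks (percent, with 95% exact binomial intervals) that overlap a replicate 3 region, and share with a WGATAR site within 50 bp of the summit, in bins of equal size from the highest to the lowest signal. The overlap falls from 78.3% to 46.3%, and the WGATAR share stays between 34.1% and 36.1%.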

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

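The test of the elt-3 neighbourhood in replicate 3 was chosen after the region counts there had been seen, and the other tests in this part were written before their results.

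Mitochondrial DNA held 24 thresholded peaks, which no comparison with genes used; they stood out as signal in data outside the main measurement. They covered 51.9% of the mitochondrial genome, the strongest had a signal of 1090, and 14 of the 20 strongest regions of replicate 3 were mitochondrial, against 3 of 20 in replicate 1.

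Peaks at ribosomal protein genes were among the strongest, yet few of them held a GATA site. Only 7.02% of the 57 summits had WGATAR within 50 bp (interval 1.95 to 17.004), against 35.4% of the other nuclear summits. That gap is not corrected for base composition, since these summits had a GC content of 50.4% against 43.0%. Their flanks held the site at 12.3%, against 21.1% for flanks of the other summits. The low share itself argues against direct binding to GATA sites as their main source. It was 0.571 times the share in their own flanks, on 4 summits with a site. Signal at very active promoters that does not rest on such a site would give this. Such signal may come from the assay itself or from other bound proteins, and without a control immunoprecipitation among the files those cannot be separated. Apart from binding to GATA sites, no biological explanation was tested, since the design has no second group.

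Of the thresholded peaks, 41.3% had no region in the list of replicate 3. The share with one was 31.9 percentage points higher in the fifth of nuclear peaks with the highest signal than in the lowest. Weaker enrichment or lower depth in replicate 3 would give such a rise, although the depth itself is unknown. The signal comes from the pool, which includes replicate 3, so the rise does not tell this explanation from others. A replicate 3 library from a strain without the tagged elt-3 transgene stays open: it held 38 regions in the 40 kb around elt-3, against at most 29 in 998 random windows, or 41 with 2 windows that overlap the elt-3 neighbourhood, which were left out after that first result. Those regions speak for the transgene only if they come from it, which is undecided, as is whether the antibody recognised GFP or ELT-3. The labels also give the libraries different sources of worms and fragmentation notes, a difference that was not tested, and no biological explanation was tested.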

How the results depend on the processing

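Of 234 gene list values under alternatives, 188 kept their direction and side of the threshold, 21 lost the call, 5 gained it and 20 changed direction. The alternatives that split peaks by GATA site or asked for a region in each replicate's list, and all those for the RNA gene classes, were chosen after seeing the data. Chemoreceptors, the RNA gene classes, the share near 5′ ends, the X excess and the GATA ratio kept direction and call under every alternative run for them. For the GATA ratio this was only just so in replicate 3 alone (1.12, exact p = 0.0496 by the McNemar test). Values below are odds ratios, or ratios to random lists, unless named otherwise, and the cause of a change was not tested. A change of direction is one of the value alone, and its interval may still include 1. The 1470 peaks of highest signal gave 1000 coding genes, an antimicrobial peptide value of 3.56 without the call, and 0 for molting and for epidermal transcription factors, in the other direction. The intervals of these values of 0 reached 3.30 and 3.85, so they do not show a reversal. The 1722 peaks with a region in each list gave 1092 coding genes. With those peaks the call was lost for molting (3.65), the transcription factors (4.33) and tyrosine catabolism (8.66), and the direction changed for junctions (0.864), neurons (1.02) and histones (1.57). Peaks with WGATAR gave collagens (3.13) and osmotic stress (9.41) the call, took it from ribosomal proteins (2.90) and the transcription factors (4.69), and changed the direction for cuticlins (1.03), junctions (0), muscle (1.202) and histones (2.49). Peaks without WGATAR changed the direction for collagens (0.779), tyrosine catabolism (0) and neurons (1.18) and ended the call for molting (1.95), the transcription factors (3.25) and the peptides (2.43). The intervals reached 8.09 for junctions with WGATAR and 11.0 for tyrosine catabolism without it. The window of 500 bp upstream to 250 bp downstream ended the call for molting (3.56) and the transcription factors (3.20). The window of 2000 bp upstream ended it for the transcription factors (3.04), gave it to collagen processing (5.07) and junctions (4.37), and put histones at 1.01. A background of named genes ended the call for molting (3.27), the transcription factors (3.20) and the peptides (3.45). Nearest-gene assignment lowered ribosomal proteins to 10.8 with the call kept, gave osmotic stress the call (3.84) and put neurons at 1.18, and matched random lists put neurons at 1.08. Counting linked members once put the transcription factors at 3.17 without the call (adjusted p = 0.0617) and histones at 2.07 (0.0240, permutation tests). Neither p is taken to settle a call, since junctions at 2.15, with as many clusters as histones, had 0.192 by the same test. Across the replicates alone, coding genes with a peak ranged from 1173 to 1881 and enriched 6-mers from 161 to 731. Tyrosine catabolism ranged from 3.21 to 19.3, molting from 3.40 to 4.47, the transcription factors from 1.70 to 4.02, the peptides from 3.44 to 7.43, collagen processing from 0 to 1.92, cuticlins from 0.234 to 1.23, GATA factors from 0 to 1.60, junctions from 0 to 2.27, hedgehog-related genes from 0.468 to 0.989, muscle from 0 to 0.457 and neurons from 0.565 to 0.943. The share of top regions common to the replicates was 17.4% with 50% reciprocal overlap, 17.01% for summits within 100 bp and 29.8% for the top 1000 regions, and Pearson's r of log2 signal was 0.441. A stricter reproducibility score could not be applied, since the thresholded list holds none that varies. Read depth is unknown, so what it limits cannot be stated.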

Other observations

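The tests of elt-3 copies and of the X motif in this part were chosen after related results had been seen, as were the name families, the lists split by GATA site and the flank and ribosomal-protein checks of the epidermal odds ratio. The test that joins 6 epidermal lists and the test of GAGAGA against WGATAR were written before their results.

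Beyond the fixed lists, gene families with shared names differed in how often they had a peak. Of 175 name families with at least 10 members, 14 had peaks more often than other coding genes and 10 less often (Fisher's exact test, adjusted over the families). Besides the ribosomal families, peaks lay at 12 of 25 eif genes for translation initiation factors (odds ratio 8.94, adjusted exact p = 2.6e-05), 7 of 13 rpn genes for proteasome subunits (11.3, 0.0017), 5 of 11 rpb genes for RNA polymerase subunits (8.05, 0.0202) and 10 of 31 vps genes for vesicle sorting (4.61, 0.0072). The dpy genes, named for a short, stout body shape, had 8 of 25 (4.55, 0.0189). Of these, dpy-7 and dpy-10 were on the cuticle collagen list and dpy-11 and dpy-31 on the collagen processing list. The others, dpy-6, dpy-23, dpy-27 and dpy-30, were on neither, so this is not a result about the cuticle alone. Of the 240 clec genes for C-type lectins, 1 (clec-126) had a peak (0.0398, 1.3e-07), and F-box genes of the fbxa family had 5 of 170 (0.290, 0.0202).

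Counting only peaks with a WGATAR site changed which lists passed. Cuticle collagens then had 12 of 176 genes with such a peak (odds ratio 3.13, adjusted exact p = 0.0052), osmotic and oxidative stress genes 4 of 22 (9.41, 0.0065), molting genes 4 of 23 (8.92, 0.0065), antimicrobial peptides 3 of 19 (7.93, 0.0275) and tyrosine catabolism 4 of 6 (84.7, 3.7e-05), while ribosomal proteins fell to 2.90 (0.0903). Epidermal transcription factors lost the call (2 of 20; 4.69, adjusted exact p = 0.173), collagen processing had 1 of 12 (3.83, 0.443) and junctions had 0 of 21. Among coding genes with a peak, those with a GATA-bearing summit belonged more often than those without to 6 lists joined (collagens, collagen processing, molting, epidermal transcription factors, antimicrobial peptides and junctions): 22 of 464 against 23 of 1414, an odds ratio of 3.01 (interval 1.58 to 5.71, exact p = 0.00037). This joined value does not describe each list, since junctions had no GATA-bearing peak. Genes that share a peak, such as nlp-31 and nlp-34, were counted separately. The interval and p treat them as independent, although the site belongs to the peak. Leaving out ribosomal protein genes gave 2.92 (interval 1.54 to 5.55), and sorting the same peaks by a WGATAR site 500 bp to the left of the summit gave 0.531 (0.182 to 1.27). The hypothesis tested was that peaks with a GATA site lie at epidermal genes more often than peaks without one. It concerns a rate and not a majority, since 23 of these epidermal genes had only peaks without a site. The joined value was not computed for either replicate alone.

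GAGA-type and GATA-type sequences did not part the peaks into separate sets: summits with GAGAGA held WGATAR about as often as the others (35.5% against 34.6%; odds ratio 1.04, interval 0.867 to 1.24). On X, the core CGCAGGG of the motif known for recruiting the dosage compensation complex lay at 16 of 611 summits, against 14 of 2305 on autosomes (odds ratio 4.40, exact p = 8.6e-05). Without the summits that held it, X still had an odds ratio of 1.64 (interval 1.48 to 1.81). Summits with this exact core were too few to make up the excess on X, whatever the motif does. The test therefore cannot exclude the full motif, which was not sought.

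Regions were crowded around elt-3. The pooled list had 47 in the 40 kb centred on the gene, against a median of 11 in 998 random windows, of which 1 held as many. Extra copies of the region carried by the transgene, unmatched in the control, could give this crowding, but a random window of equal count keeps the test undecided, and no biological explanation was tested. Around unc-119 there were 9.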
